A study of Mus musculus with 1000 samples.

How the data were processed

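Per the labels' protocols, male C57BL/6NCrl founders were treated with ENU and third-generation offspring were collected, with brain RNA extracted after removal of the cerebellum. Libraries were made with a 3' cDNA kit in which every sample of a plate row carries its own in-line index, per the labels' protocols. The samples of a row were combined into a 12-plex pool, and 96 such pools were mixed into an 1152-plex sequencing library, per the same protocols. Per the submitters' processing notes, GSNAP was used and the genome build was GRCm38. Versions and the counting method were not given in the sources used here.

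The deposited table analysed here was made by the authors as a lookup from library name to the part of the processed data that holds the library. Its part column names 3 parts and has 0 numeric cells, so it gives no counts, depths or normalised values. Expression values were not analysed here, and the planned comparison of expression between families, with its lists of microglial, astrocytic, oligodendrocyte, neuronal, vascular, choroid plexus and interferon-response genes, was not run. The rule for naming genes, fixed with those lists, was to name the 10 genes with the largest change past an adjusted p of 0.05, and none if the table held no expression values. The table has 23231 lines, of which 22231 are libraries outside this set and were not used. No reference annotation was used.

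The family code, animal number, plate, well and pool number were read from each library name, and the number after the letter S was taken as the pool number. The labels define none of these fields. The S number was read as the pool because the 86 plate rows and the 86 S numbers matched one to one, and the protocol combines each plate row into a pool. The reading of the trailing digits as an animal number rests on the labels' statement that third-generation mice were collected, which sets apart the preceding G3. The library names had been read before the tests were fixed, so the tests of layout describe an arrangement that had already been seen. The other settings were fixed with the names known and before the lookup table was examined. The well-order alternative, the shuffles within plates, the tally of steps at which the animal number fell and the example given with it were chosen later.

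For families and pools, the statistic was the percentage of same-code library pairs lying in 1 pool, and the codes were shuffled over all libraries 100000 times. For animal number and plate column, Spearman's rho was computed in each code with at least 3 libraries and averaged, and animal numbers were shuffled within codes 100000 times. Both tests were two-sided with a threshold of 0.05 and were run in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3. The plot was drawn with matplotlib 3.10.9. The pool statistic was tested on simulated data: it returned 100% for families kept whole, and 7% of 100 random layouts fell under the threshold. The simulated families and pools were all of equal size, had no plates and were tested with fewer shuffles. They therefore check the code and do not calibrate the test on the observed layout. The values are complete tallies of the library names in this set, so for this set they carry no sampling error. Libraries outside the set could change them. The depth of the libraries is unknown here.

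Alternatives were a pool defined by plate and row, exclusion of the plate with the suffix rep, restriction to codes with 12 libraries, Pearson's r in place of rho, a match of names on letters and digits alone, and exclusion of each library of the 2 codes with 3 libraries in turn. For rho, leaving out a library of those 2 codes took the code below the minimum of 3 libraries and so removed it whole. Alternatives using well order and shuffles within plates were added after the data were seen.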

Results

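Brain RNA libraries from 1000 mice of an ENU mutagenesis screen were examined for how they were laid out, since the table at hand names libraries and holds no expression values. ENU (N-ethyl-N-nitrosourea) is an alkylating agent that induces point mutations in the germ line of treated males. The screen bred such mutations to homozygosity from treated C57BL/6NCrl founders and looked for abnormal inflammatory states in the brain transcriptome. The expression values of the series are held separately, in the parts to which the table points. Expression levels, sequencing depths and genotypes were not analysed here, so no gene is named and no difference in expression between families is reported. Every library was made from brain tissue without the cerebellum, and all of them carried the same labels apart from the library name. The labels do not define the parts of the name, which were read here as a code after the letters ENU, an animal number, a well, a plate and, after the letter S, a cDNA pool number. The reading of the S number as the pool rests on its match to the plate rows: the libraries lay in 86 plate rows, and each row had 1 S number of its own. Libraries sharing a code were taken as 1 family.

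The 1000 libraries fell into 89 family codes, and each combination of code and animal number occurred once. In 78 codes there were 12 libraries, which together made up 936 of the 1000 libraries. Of the other 11 codes, 2 had 8 libraries, 7 had 6 and 2 had 3. These sizes count the libraries of this set only. Libraries outside it may carry the same codes, and their names in the lookup table were not searched for them. The animal numbers reached 38, the highest number within a code had a median of 18, and 84 of the 89 codes held an animal number above 12. The libraries came from 12 plates. A plate named with the suffix rep contributed 20 libraries from 4 codes, and the other 11 plates contributed between 66 and 96 libraries each. No animal on the plate with the suffix rep had a further library among the 1000, so agreement between repeated libraries of 1 animal was not assessed.

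The first comparison asked whether families were separable from the cDNA pools in which their libraries were prepared. Each of the 12 columns of a plate row receives its own in-line index before the row is combined into 1 pool, so libraries of a pool share all later steps up to the final mixing. Families and pools were almost the same division of the libraries. All 78 codes with 12 libraries occupied a whole pool of 12, and 88 of the 89 codes lay in 1 pool. Of the 5315 pairs of libraries with the same code, 5313 (99.96%) lay in the same pool. When codes were shuffled over the libraries, a mean of 1.08% and at most 1.77% of such pairs shared a pool (two-sided permutation test, 100000 shuffles, p = 1e-05, the smallest value these shuffles can give). That chance value includes the division of families by plate. When codes were shuffled within plates only, a mean of 12.6% and at most 14.6% of such pairs shared a pool (two-sided permutation test, 100000 shuffles, p = 1e-05, again the smallest possible value). The names had been read before these tests were fixed, so p describes only a departure from random placement.

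The exceptions were few. Among the 86 pools, 82 held 1 code and 4 held 2 codes. Pool 31 combined 6 libraries of ENU55362 with 6 of ENU56007, and pool 56 combined 6 of ENU55176 with 6 of ENU56067. On the plate with the suffix rep, pool 95 held 6 libraries of ENU55163 and 2 of ENU55147, and pool 96 held 8 of ENU55182 and 3 of ENU55186. The remaining library of ENU55147 was in pool 94, which made this the only code divided between pools. Different codes therefore met within a pool in 108 of the 5421 same-pool pairs (1.99%), and 81 of the 89 codes shared no pool with another code. For those 81 codes, the family and the pool cannot be told apart from these libraries alone. Pools with fewer than 12 libraries here, of which there were 6, may also have held libraries that were not analysed here. Among the 81 codes, ENU55262, ENU55352 and ENU56298 lay in such pools. Whether each of them was alone in its full pool is unknown here.

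Families were divided from one another by plate as well, since all 89 codes lay within 1 plate. Counting the libraries of this set only, a plate held between 4 and 9 codes, and 7 of the 12 plates held 8. The plate with 4 codes was the one with the suffix rep, of which 20 libraries in 3 pools were in this set. Families on the same plate can thus be compared without a difference in plate. Outside the 4 pools that held 2 codes, they cannot be compared without a difference in pool. Within each of those 4 pools, the 2 codes lay in separate blocks of columns, so the families still differed in their in-line indexes.

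The second comparison asked whether the in-line index was distributed evenly over families. The labels do not give the index of each library, so the plate column was taken to stand for it. Each of the 78 codes with 12 libraries used all 12 columns, which follows from each filling a whole plate row. The columns held between 82 and 85 libraries each, as 80 pools were full. Codes with fewer than 12 libraries necessarily left columns unused. Within families, however, the position was ordered by animal number. Spearman's rho between animal number and plate column was 0.87 ± 0.25 (mean and SD over 89 codes), with a median of 1, and it was above 0 in 88 codes. Shuffling animal numbers within codes gave mean values between -0.18 and 0.17 (two-sided permutation test, 100000 shuffles, p = 1e-05, the smallest value these shuffles can give). The order, too, had been seen in the names before this test was fixed. In 53 of the 88 codes lying in 1 pool, the animal number rose at every step from one occupied column to the next. ENU56298, with 8 libraries, was among them, but its columns had gaps. Its animal 2 lay in column 2 and its animal 3 in column 6. Any other animal of this code in the columns between would make the animal number fall at a step. The single negative value, -0.50, belonged to ENU55147, whose 3 libraries lay in 2 plate rows. Counted in well order over rows and columns, its 3 animal numbers rose throughout, with rho = 1.

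**Figure D1:**
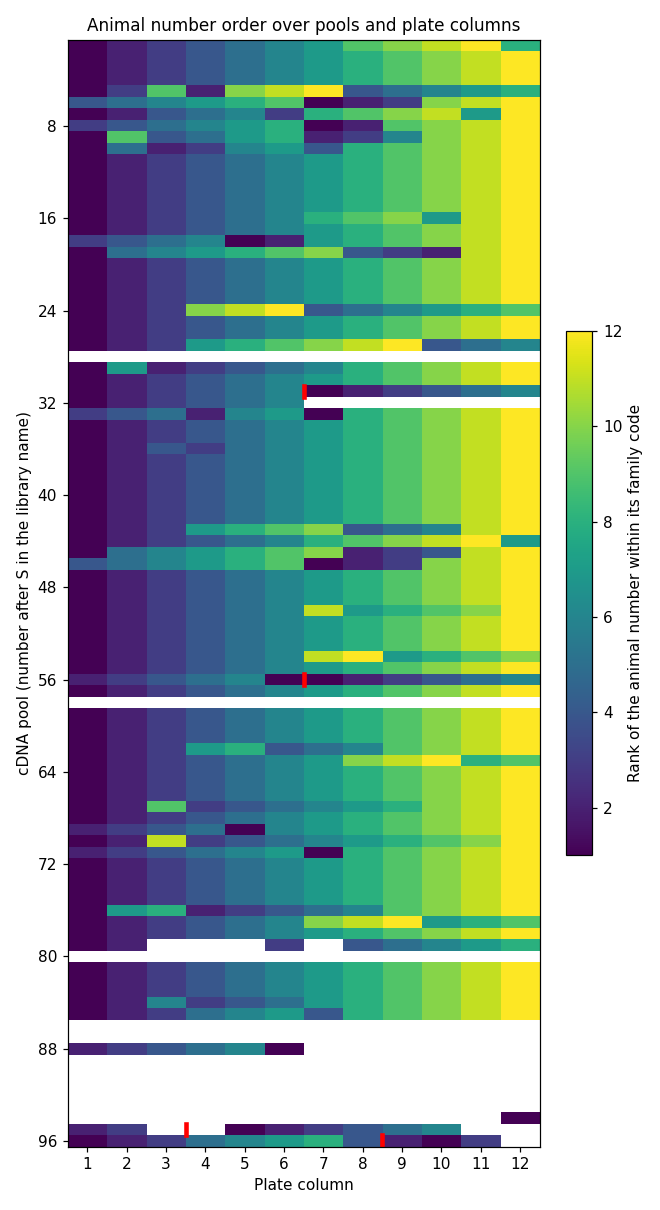
Position of the 1000 libraries by plate column (horizontal axis, 1 to 12) and cDNA pool number (vertical axis), coloured by the rank of the animal number within its family code. White cells hold no library of this set, and red bars mark the border between 2 codes in the 4 pools that held more than 1 code. Most rows run from low to high rank across the 12 columns, as in the 53 codes whose animal number rose at every step.

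The third comparison asked where the processed values of each library are held. All 1000 library names matched exactly 1 line of the lookup table, and all of them were assigned to 1 of its 3 parts. Families were therefore not divided between parts, with 100% of same-code pairs in the same part. With 1 part for all libraries, no test of families against parts was possible.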

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

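Over 10 alternatives, the mean correlation of animal number and plate column ranged from 0.85 to 0.90. The lower value was a mean Pearson's r, and the upper was a mean rho in codes of 12 libraries. Each alternative had a permutation p = 1e-05, the smallest value the shuffles can give. The alternatives were not all distinct, since leaving out any library of a code with 3 libraries removed that code whole. The mean rho was 0.89 without ENU55147 and 0.87 without ENU55186, whichever library was left out. With the well order, which was chosen after seeing the data, the mean rho was 0.89. For the share of same-code pairs in 1 pool, most alternatives could not have given another outcome and say nothing about stability. Plate rows and S numbers are the same division of the libraries, so defining the pool by plate and row repeats 99.96%. The only 2 pairs that lay in different pools involve the library of ENU55147 in pool 94, so leaving out that library, its plate or all codes with fewer than 12 libraries gives 100% by construction. Shuffling codes within plates, chosen after seeing the data, raised the chance share from 1.08% to 12.6% and left p at 1e-05. A match on letters and digits alone found 1000 libraries, and the 980 libraries outside the plate with the suffix rep each matched 1 line. All libraries lay in 1 part, so the alternatives for the parts could not differ from 100%, and the planned test was not run. No paired analysis was possible because the table used here holds no measured value per library.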

Other observations

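The steps at which the animal number fell from one occupied plate column to the next were tallied in the 88 codes that lay in 1 pool. This tally was chosen after the layout had been seen. It fell at no step in 53 codes, at 1 step in 29, at 2 steps in 5 and at 3 steps in 1. ENU56197, chosen as an example after its values were seen, ran 1, 2, 3, 7, 8, 9, 10, 12, 13 and then 4, 5, 6. Whether the 35 codes with at least 1 fall follow an order of their own was not tested.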
